A study of Homo sapiens with 12 samples.

How the data were processed

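Small RNA libraries were sequenced from HGC-27 and AGS, established human gastric cancer cell lines, after 24 h with 5 µM SAHA or with its solvent DMSO. SAHA (vorinostat) inhibits histone deacetylases. Each of the 4 groups held 3 replicates, so 12 libraries were analysed, all of those the labels list. The labels number the replicates from 1 to 3 but do not say whether they were separate cultures, so every p-value measures only the spread between these samples, which may be technical. Total RNA was extracted with TRIzol and the libraries were made with the NEBNext small RNA kit, per the labels.

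The submitters' processing notes name cutadapt, without a version, and Novoalign 2.07.11. The genome build, the microRNA database release, the counting rule and the program behind the predicted entries are not given in the sources used here. The authors deposited whole-number tag counts, the unit of the first table, with all isoforms of a mature microRNA summed for each hairpin, and a blank where nothing was listed. The smallest listed count was 2, so blanks were read as 0 and a listed 0 is not proof of no reads. The second deposited table held a score: the authors' scaling of the same counts to CPM, rounded to whole numbers, whose columns summed to between 983286 and 991838. It left some raw counts of up to 15 blank and was used only for an alternative.

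The count table had 2909 entries. Of these, 2049 carried the name of an annotated microRNA, for 1906 mature names, and 860 were predicted entries with no annotated name. For 111 mature names more than 1 hairpin was listed, and the hairpin with the highest total over the 12 libraries stood for the name. The predicted entries were left out of the main comparisons and tested apart. In what follows the species prefix of the names is left out. Positions came from the GENCODE 29 annotation, matched by the hairpin's gene symbol, which gave a position for 545 of the 608 microRNAs tested. It was not used for counting.

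Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalization and the filterByExpr filter over the 4 groups, which left 608 microRNAs. edgeR's quasi-likelihood test was run on 1 fit of all 12 libraries with 1 coefficient per group and 8 residual degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over the 608 microRNAs in each comparison, and a microRNA was called at an adjusted p under 0.05. The comparisons were SAHA against DMSO in each line, the difference between the responses of both lines, and AGS against HGC-27 under DMSO. Overlap of calls was compared with the number expected if the lines were independent, and with one-sided Fisher's exact tests. Levels are TMM-scaled CPM, given as the mean ± SD of 3 libraries. Log2 fold changes are those of the edgeR fit. Where all 3 libraries of a group listed nothing, the fold was computed against a floor of 3 counts per library and is a lower bound. Where the lower group held 1 to 3 counts in all, the ratio of summed counts is given with its exact 95% interval. These intervals read blanks as 0, so their lower limits are not on the scale of the bounds. Since a blank can stand for 1 count, the lower limit with 1 count in each blank library was computed as well. Such bounds and intervals rest on the sum or mean of the 3 libraries of a group. They cover counting error only and leave out the spread between libraries. The libraries also had no molecular identifiers.

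Before the data were examined, 25 lists of microRNAs were fixed (families, clusters, microRNAs reported as silenced in gastric cancer, and markers of other cell types), together with the tests, the rule for naming microRNAs and the first set of alternative settings. The 24 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. camera was also run with an estimated correlation, and fry was run beside it (limma 3.58.1). Member counts are given over all microRNAs tested and adjusted over the list alone.

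The microRNAs named were chosen by 5 parts of a rule. The first part took, for SAHA against DMSO in each line and for the line baseline, the 8 higher and 8 lower calls with the largest absolute log2 fold change, a mean of at least 10 CPM in the higher group and no overlap between the groups' replicates. The second took the 6 most abundant microRNAs of each comparison and the 6 most abundant calls changed by 1.5-fold or more. The third took the 5 largest differences between the lines in each direction among calls of at least 10 CPM in any group. The fourth took the 4 most abundant members of each list described. The fifth took, from the calls shared by both lines, the 5 in each direction with the highest smaller absolute log2 fold change and at least 10 CPM in the higher group of each line. Any other microRNA named was chosen after its values were seen.

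The tests were checked on simulated data. In a simulation of HGC-27 with 543 microRNAs tested, the edgeR test recovered 63 of 93 microRNAs changed 2-fold (67.7%) and 79 of 87 changed 4-fold (90.8%), and called 5 of 363 unchanged ones. In AGS, with no change simulated, it called 2 of 543. camera gave a planted list an adjusted p of 1.45e-10 and called 0 of 20 unchanged lists. The simulated microRNAs were drawn independently, whereas members of some real lists were correlated (estimated at 0.58 for the DLK1-DIO3 cluster in HGC-27). The simulation therefore does not show how often camera calls unchanged lists in the real data.

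The alternative settings fixed at that point were median-of-ratios size factors, plain totals, a looser and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the authors' normalized values plus 1, robust empirical Bayes, only the 6 samples compared, a 2-fold minimum, the replicate number as a block, the more abundant arm of each hairpin alone for the list tests, and leaving out each replicate. Those added after seeing the data were all deposited entries, the sum over a name's hairpins, annotated and predicted entries fitted together, and leaving out 3 libraries that stood apart (HGC-27 SAHA 2, HGC-27 DMSO 1 and AGS DMSO 2). Figures were drawn with matplotlib 3.10.9.

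Plain totals, in place of TMM, moved the median log2 fold change of all 608 microRNAs by 0.12 in HGC-27 (from 0.08 to 0.19) and by 0.19 in AGS (from 0.08 to 0.26). Every change with SAHA is therefore relative to the other microRNAs of the library and holds no information on the total amount of microRNA per cell.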

Results

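MicroRNA levels were measured by small RNA sequencing in 12 libraries from HGC-27 and AGS cells, 3 for each line with 5 µM SAHA for 24 h and 3 for each line with DMSO. The series asks how this histone deacetylase inhibitor changes microRNAs in gastric cancer cells. Total counts per library lay between 2665109 and 6525388. In the order of the replicate numbers they were 4014267, 3331650 and 5357329 for HGC-27 SAHA, 4656495, 5397663 and 6525388 for HGC-27 DMSO, 2756985, 3176607 and 3487282 for AGS SAHA, and 4220848, 3695457 and 2665109 for AGS DMSO. Each library listed between 735 and 940 annotated microRNAs. A single microRNA, miR-21-5p, made up 23.7% to 39.6% of the annotated counts, and the 10 most abundant made up 59.5% to 68.8%. Every level below is a mean ± SD of n = 3 libraries in CPM, and every adjusted p comes from edgeR's quasi-likelihood test. The first 3 principal components held 39.5%, 34.9% and 8.47% of the variance. On the first, HGC-27 SAHA 2 (-19.6) lay near the AGS SAHA libraries (-19.01 to -13.91) and far from its replicates (-0.95 and -5.26). On the second it lay highest (21.2), above its replicates (14.85 and 14.58). On the third it lay lowest (-13.9), with AGS DMSO 2 next (-6.98) and its replicate HGC-27 SAHA 1 highest (10.9).

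In HGC-27, SAHA raised miR-449c-5p, a relative of the tumour suppressor miR-34a, from 14.3 ± 2.27 to 302 ± 9.46 CPM (log2 fold change 4.40, adjusted p = 2.35e-07). The epithelial microRNAs miR-192-5p and miR-194-5p rose from 1362 ± 336 to 5674 ± 100.4 CPM (2.06, adjusted p = 8.8e-04) and from 151.8 ± 50.5 to 537 ± 33.7 CPM (1.82, adjusted p = 2.06e-04). miR-7-5p, 1 of the most abundant microRNAs of the line, rose from 17680 ± 2826 to 51270 ± 2888 CPM (1.54, adjusted p = 2.57e-05). Members of the oncogenic miR-17 to miR-92 cluster fell, with miR-20a-5p going from 23250 ± 2070 to 12140 ± 2266 CPM (-0.94, adjusted p = 9.35e-04) and miR-17-5p from 12250 ± 726 to 6632 ± 1124 CPM (-0.89, adjusted p = 9.35e-04). Of the 608 microRNAs tested, 248 were called, 132 higher and 116 lower, and 95 higher and 36 lower ones changed 2-fold or more. The 3 SAHA libraries did not overlap the 3 DMSO libraries for 352 microRNAs (57.9%, where chance gives 10%), 239 of them called.

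**Figure D1:**
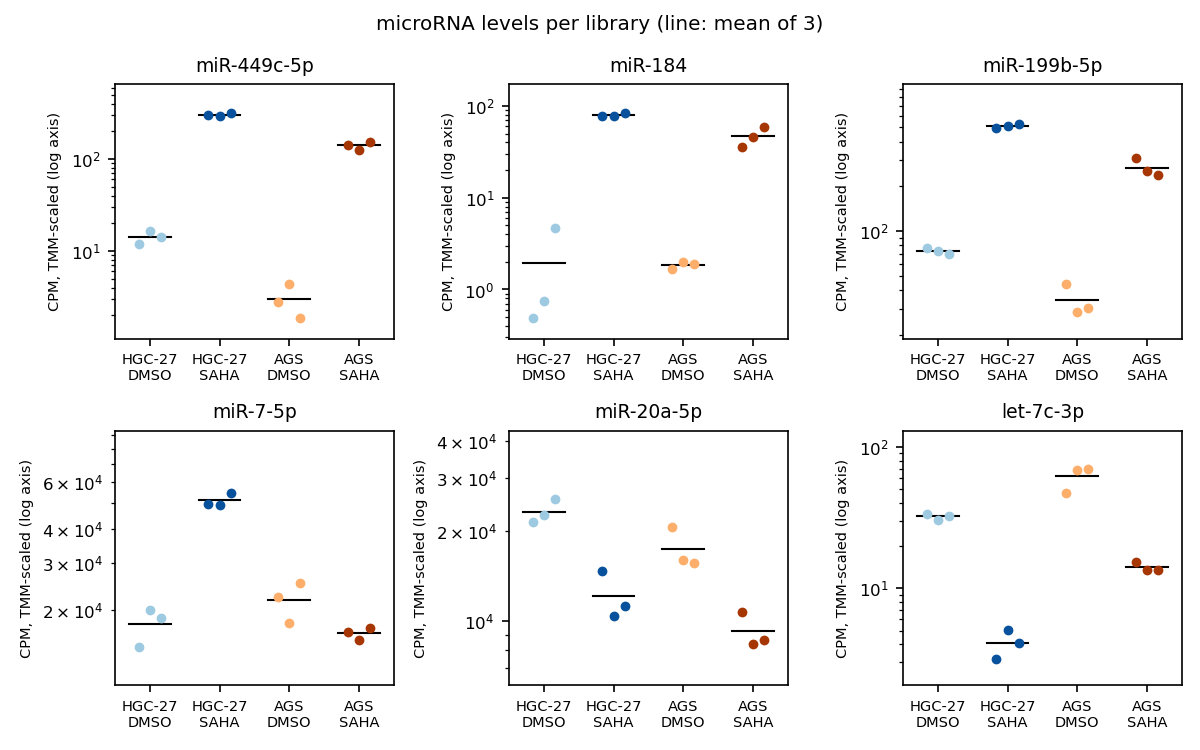
Level of selected microRNAs in each of the 12 libraries, in CPM on a log axis, with 1 point per library and the group mean as a line. For miR-449c-5p the SAHA libraries lie far above the DMSO libraries in both lines, and for miR-7-5p only in HGC-27 (mean 51270 CPM with SAHA against 17680 CPM with DMSO).

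Among the calls with the largest falls in HGC-27, let-7c-3p went from 32.2 ± 1.66 to 4.08 ± 0.95 CPM (log2 fold change -2.98, adjusted p = 6.56e-06) and miR-92a-1-5p from 69.3 ± 7.96 to 8.98 ± 2.84 CPM (-2.93, adjusted p = 3.51e-05). The other 6 large falls had log2 fold changes of -2.41 (miR-365b-5p), -2.23 (miR-16-1-3p), -1.53 (miR-1247-3p), -1.51 (miR-125a-3p), -1.41 (let-7e-3p) and -1.40 (miR-4521, from 2526 ± 209 to 956 ± 224 CPM). Of the most abundant microRNAs, miR-30a-5p fell from 69070 ± 11600 to 42390 ± 1194 CPM (-0.70, adjusted p = 0.00107), and miR-92a-3p and miR-10a-5p fell by 0.73 and by 0.71 on the log2 scale. let-7i-5p fell by 0.45 (adjusted p = 0.00427), a call lost without HGC-27 DMSO 2. miR-21-5p, at 289500 ± 36120 with DMSO and 239000 ± 14890 CPM with SAHA, missed the threshold (-0.28, adjusted p = 0.0548), although DESeq2 called it. miR-148a-3p (0.65, adjusted p = 0.225) and let-7g-5p (-0.05, adjusted p = 0.695) were not called.

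The largest rises in HGC-27 rested in large part on 1 library. miR-891a-5p, listed in no DMSO library, stood at 10.7 ± 1.97 CPM and was at least 15.6-fold higher, with like levels in all 3 SAHA libraries (adjusted p = 4.22e-05). For the other 7 of the 8 largest rises, HGC-27 SAHA 2 far exceeded its replicates: miR-138-5p, at least 36.7-fold higher, stood at 73.2 CPM there and at 1.25 and 1.36 CPM in the other SAHA libraries. The ratio of counts was 230.4 for miR-124-3p (95% interval 78.4 to 1121), 119 for miR-708-5p (32.5 to 990.2), 98.5 for miR-495-3p (33.3 to 481) and 77.7 for miR-323a-3p (21.04 to 648.5). HGC-27 SAHA 2 held miR-495-3p at 74.6 CPM and miR-323a-3p at 32.3 CPM, against at most 4.76 and 6.8 CPM in the other SAHA libraries. With 1 count in each blank library the lower limits were 58.9, 22.9, 24.95 and 14.8 for miR-124-3p, miR-708-5p, miR-495-3p and miR-323a-3p. Without HGC-27 SAHA 2, miR-138-5p, miR-124-3p and miR-708-5p were no longer called (adjusted p = 0.0544, 0.0849 and 0.0781). The log2 fold change moved from 6.50 to 4.09 for miR-370-3p (adjusted p = 0.00619) and from 6.14 to 2.61 for miR-127-5p (adjusted p = 0.0201), both still called. The call of miR-124-3p also ended without any 1 of the 3 DMSO libraries, and that of miR-708-5p without HGC-27 DMSO 3.

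Of the 24 lists tested in HGC-27, 9 passed camera's preset test, and none passed with an estimated correlation. Of the 21 tested members of the miR-17 to miR-92 cluster and its paralogs, 16 fell and 1 rose, miR-363-3p (adjusted p = 1.3e-04, and 0.178 with an estimated correlation). Adjusted over the list alone the counts were also 16 and 1, and without HGC-27 SAHA 2 they were 10 and 1. Of the 20 tested members of the let-7 family, which restrains growth-promoting genes in many tissues, 12 fell and 0 rose (adjusted p = 1.3e-04, and 0.178 with an estimated correlation), or 13 adjusted over the list alone. The abundant let-7b-5p went from 10990 ± 973.5 to 7239 ± 344 CPM, whereas let-7f-5p stayed at 27390 ± 2156 and 25540 ± 1340 CPM (adjusted p = 0.375). Of 11 tested members of the miR-99, miR-100 and miR-125 list 8 fell, among them miR-100-5p by 0.57 and miR-99b-5p by 0.78 on the log2 scale (adjusted p = 7.37e-04, and 0.0883 with an estimated correlation). Of 11 miR-30 members 6 fell, with miR-30a-3p going from 5357 ± 222 to 3510 ± 147 CPM (adjusted p = 0.0165, and 0.299 with an estimated correlation). Without HGC-27 SAHA 2 only 3 of them were called lower (adjusted p = 0.0372), and the list lost its call with the more abundant arm of each hairpin alone (adjusted p = 0.0598). With plain totals in place of TMM these 4 lists kept a negative median, with 10, 10, 6 and 5 members called lower.

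Of the 6 tested members of the miR-34 and miR-449 family, which slows the cell cycle, the 3 of the miR-449 cluster rose (miR-449a, miR-449b-5p and miR-449c-5p) and miR-34a-5p fell from 721 ± 98.6 to 467 ± 6.79 CPM (adjusted p = 0.00268, and 0.0896 with an estimated correlation). Adjusted over the list alone, 4 rose and 1 fell. The hairpin of miR-449c lies on chromosome 5 between 55172262 and 55172353, in an intron of CDC20B, and that of miR-449a between 55170532 and 55170622, in the same gene. Of 4 tested members of the miR-192, miR-194 and miR-215 list, known from gut epithelium, 3 rose: miR-192-5p, miR-194-5p and miR-194-3p (adjusted p = 0.00992, and 0.317 with an estimated correlation). The call of the list was lost with the more abundant arm of each hairpin alone (adjusted p = 0.0532). miR-215-5p was not called (72.3 ± 83.1 and 100.1 ± 37.2 CPM). Its mean with DMSO rested on HGC-27 DMSO 1, which held 167.9 CPM against at most 30.4 CPM in its replicates. Without the 3 libraries that stood apart, 4 of the 4 tested members of this list were higher (adjusted p of the list 1.57e-06 in camera's preset test). Of 8 fibroblast and smooth muscle markers 3 rose (adjusted p = 0.0165, and 0.422 with an estimated correlation). They were miR-199b-5p, from 73.5 ± 3.61 to 512 ± 13.8 CPM, and miR-199a-3p and miR-199b-3p, whose counts were nearly the same, since these mature sequences share their reads. miR-143-3p, the most abundant marker of the list, was not called (388 ± 539 and 647 ± 698 CPM), and the list lost its call without HGC-27 SAHA 2 (adjusted p = 0.181). Without the 3 libraries that stood apart, among them HGC-27 DMSO 1, it had 4 members higher (adjusted p = 1.66e-04).

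The imprinted DLK1-DIO3 cluster on chromosome 14 had 23 of 25 tested members called higher and 0 lower in HGC-27, or 24 adjusted over the list alone (adjusted p = 1.3e-04, and 0.422 with an estimated correlation). HGC-27 SAHA 2 stood apart here: it held miR-381-3p at 1793 CPM where the other SAHA libraries held 49.4 and 56.2 CPM and the DMSO libraries 7.91 to 17.8 CPM. Without it, 13 members were called higher (adjusted p = 5.24e-04) and miR-381-3p kept a log2 fold change of 2.08 (adjusted p = 0.00337), in place of 5.60. Without the 3 libraries that stood apart, 9 members were called higher (adjusted p = 8.98e-04). Without HGC-27 SAHA 2, miR-379-5p kept 2.16 (adjusted p = 0.0288), whereas miR-411-5p and miR-127-3p lost their calls. Of 21 tested microRNAs reported as silenced by DNA methylation in gastric cancer, 12 rose and 1, miR-181c-3p, fell (adjusted p = 0.0165, and 0.422 with an estimated correlation). In HGC-27 SAHA 2 miR-9-5p of this list stood at 2658 CPM against 72.8 and 236 CPM in its replicates, and without this library 7 members rose (adjusted p = 0.0367), and 5 without the 3 libraries that stood apart (adjusted p = 0.00437). The call of the list was lost with the more abundant arm of each hairpin alone (adjusted p = 0.119). The list shares miR-127-3p and miR-127-5p with the DLK1-DIO3 cluster, miR-195-3p, miR-195-5p and miR-497-5p with the miR-15 and miR-16 family, miR-181c-3p and miR-181c-5p with the miR-181 family, and miR-10b-3p and miR-10b-5p with the HOX cluster microRNAs. It also shares miR-34c-5p with the miR-34 and miR-449 family and miR-124-3p with the markers of muscle, liver and neurons.

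The other 15 lists tested did not pass in HGC-27. The called members were miR-183-5p and miR-96-5p higher in the miR-183 cluster (5 tested, adjusted p = 0.181), miR-195-3p and miR-497-5p higher and 5 lower in the miR-15 and miR-16 family (12 tested, 0.231), and miR-29b-1-5p lower in the miR-29 family (7 tested, 0.69). In the miR-181 family (9 tested, 0.55) miR-181a-3p and miR-181b-3p were higher and 5 members lower. All 4 tested members of miR-221 and miR-222 were lower (0.0733), as were 4 of 8 in the miR-130 and miR-301 family (0.158), 4 of 8 HOX cluster microRNAs (0.12, and 0.0443 without HGC-27 SAHA 1), and miR-519a-3p and miR-522-3p of 6 in the chromosome 19 cluster (0.296). miR-27a-3p was higher and miR-23b-3p, miR-27b-3p and miR-27b-5p lower in the miR-23, miR-24 and miR-27 clusters (11 tested, 0.369). In the Xq27 testis cluster (4 tested, 0.121) miR-509-3-5p and miR-514a-3p were higher. Single members were called higher among microRNAs made without Drosha (miR-1224-5p of 6, 0.55), blood cell markers (miR-144-5p of 7, 0.835) and markers of muscle, liver and neurons (miR-124-3p of 5, 0.853). Among entries that overlap other small RNAs (8 tested, 0.884) miR-1246 was higher and miR-4454 and miR-7977 lower. The miR-200 family, a keeper of the epithelial state, had 0 of 6 tested members called (0.853), with miR-200c-3p at 100.3 ± 18.3 and 71.3 ± 3.78 CPM. The list of embryonic stem cell microRNAs had only miR-372-3p tested, which was at least 6.32-fold higher. Without HGC-27 SAHA 2, the members called lower numbered 1 of 4 for miR-221 and miR-222, 1 of 8 in the miR-130 and miR-301 family, 2 of 9 among HOX cluster microRNAs, 3 of 12 in the miR-15 and miR-16 family, 1 of 20 in the chromosome 19 cluster and 0 of 9 among entries that overlap other small RNAs, and 2 of 11 were called higher in the miR-23, miR-24 and miR-27 clusters. With plain totals and all libraries, 2 were lower for miR-221 and miR-222, 1 in the miR-130 and miR-301 family and 2 among HOX cluster microRNAs, and the miR-23, miR-24 and miR-27 clusters had 3 higher and 1 lower. Plain totals also gave 3 higher in the miR-183 cluster, 2 higher among microRNAs made without Drosha and among markers of muscle, liver and neurons, and 1 lower among entries that overlap other small RNAs. Among these called members, miR-27b-3p lost its call without any 1 of the 6 HGC-27 libraries, miR-96-5p without HGC-27 SAHA 1 or any DMSO library, miR-27a-3p without the same 4, and miR-7977 without HGC-27 SAHA 1, HGC-27 SAHA 2 or HGC-27 DMSO 1.

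**Figure D2:**
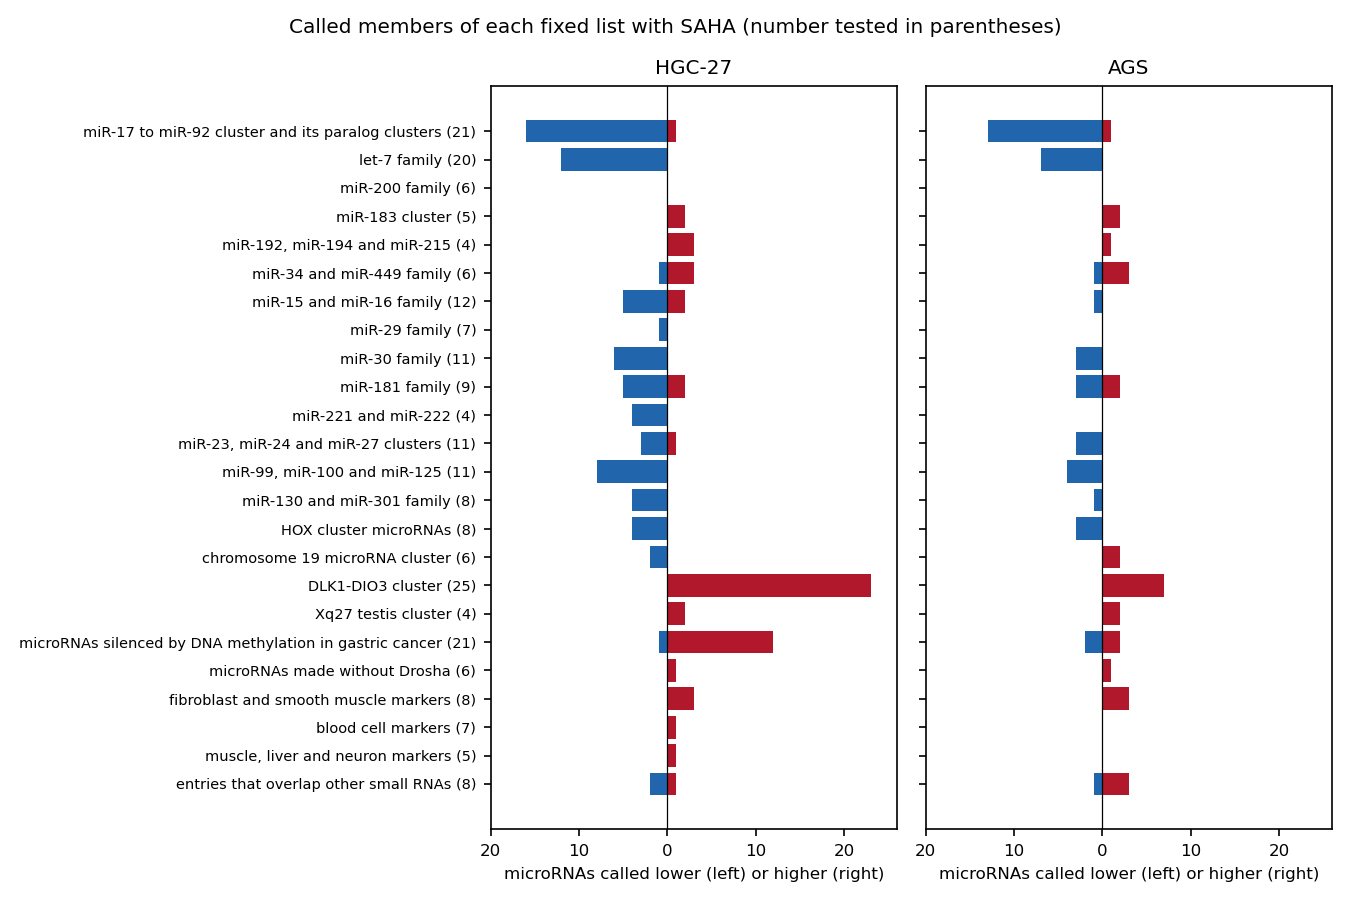
Number of members of each list called higher (to the right) or lower (to the left) with SAHA in HGC-27 and AGS, with the number tested in parentheses. The bars for the miR-17 to miR-92 cluster point to the left in both lines (16 and 13 members), and those for the DLK1-DIO3 cluster to the right (23 and 7 members).

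The count of calls in HGC-27 was 183 without HGC-27 SAHA 2, 163 without HGC-27 DMSO 3, and 173 (94 higher, 79 lower) without the 3 libraries that stood apart. With plain totals, 144 were called higher and 79 lower, whereas 115 were higher and 134 lower with annotated and predicted entries fitted together, and list tests at the preset correlation passed up to 10 lists in other splits of the 6 libraries.

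In AGS, SAHA raised miR-449c-5p from 3.00 ± 1.24 to 141 ± 14.2 CPM (log2 fold change 5.51, adjusted p = 8.82e-08) and miR-199b-5p, known from mesenchymal cells, from 34.2 ± 8.35 to 267 ± 36.9 CPM (2.96, adjusted p = 9.26e-07). miR-184 rose from 1.85 ± 0.165 to 47.1 ± 11.8 CPM (4.65, adjusted p = 3.49e-04). As in HGC-27, members of the miR-17 to miR-92 cluster fell, with miR-20a-5p going from 17450 ± 2715 to 9277 ± 1249 CPM (-0.91, adjusted p = 0.00172) and miR-17-5p from 9658 ± 1659 to 5078 ± 566 CPM (-0.93, adjusted p = 0.00112). let-7c-3p fell from 61.9 ± 12.6 to 14.04 ± 1.06 CPM (-2.14, adjusted p = 7.17e-05). In all, 161 of 608 microRNAs were called, 91 higher and 70 lower, and 51 higher and 19 lower ones changed 2-fold or more. The groups' replicates did not overlap for 235 microRNAs (38.6%, where chance gives 10%), 158 of them called.

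Several of the largest rises in AGS were of microRNAs near or below detection with DMSO. Listed in no DMSO library, miR-891a-5p at 24.2 ± 3.61 CPM was at least 22.4-fold higher, miR-483-3p at 16.6 ± 4.84 CPM at least 15.4-fold, and miR-654-3p at 16.02 ± 3.33 CPM at least 14.8-fold. The ratio of counts was 57.4 for miR-1298-5p (95% interval 15.5 to 479.5) and 56.4 for miR-449a (15.3 to 471), and miR-892a went from 3 counts to 149 (interval of the ratio 16.8 to 245). miR-370-3p (ratio 45.3, interval 12.2 to 379.8) lost its call without any 1 of the 6 AGS libraries. These intervals read blanks as 0, and with 1 count in each blank library the lower limits were 10.9 for miR-1298-5p, 10.7 for miR-449a, 12.6 for miR-892a and 8.55 for miR-370-3p. The largest falls were those of miR-181b-2-3p, from 20.6 ± 1.76 to 1.85 ± 0.809 CPM (log2 fold change -3.45, adjusted p = 2.67e-04), and miR-92a-1-5p (-2.28). They were followed by let-7c-3p, miR-19b-1-5p (-2.01), miR-152-5p (-1.89), miR-4454 (-1.81), miR-20a-3p (-1.51) and miR-195-3p (-1.38). The call of miR-195-3p was lost without AGS SAHA 1, AGS SAHA 2, AGS DMSO 1 or AGS DMSO 2.

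Among the most abundant microRNAs of AGS, miR-21-5p fell from 400800 ± 1657 to 321000 ± 36230 CPM (-0.32, adjusted p = 0.0426), a call lost with plain totals (-0.14) and without AGS SAHA 2, AGS DMSO 1 or AGS DMSO 3. Its passenger strand miR-21-3p fell from 1757 ± 56.6 to 930.1 ± 69.3 CPM (-0.92, adjusted p = 7.88e-05). let-7i-5p fell by 0.41 (adjusted p = 0.0107), a call lost without AGS SAHA 2 or AGS DMSO 3. miR-30e-5p fell by 0.73 (adjusted p = 0.00143) and miR-4521 by 1.00 (adjusted p = 0.00751) on the log2 scale. miR-126-3p, known from endothelium, went from 1646 ± 524 to 2917 ± 704 CPM (0.83, adjusted p = 0.0267), a call lost without AGS SAHA 1, AGS SAHA 3, AGS DMSO 1 or AGS DMSO 3. miR-100-5p (0.01, adjusted p = 0.946), miR-30a-5p (-0.23, adjusted p = 0.192), miR-148a-3p (0.34, adjusted p = 0.572) and miR-27b-3p (-0.16, adjusted p = 0.205, and called lower without AGS SAHA 1) were not called.

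In AGS 5 of the 24 lists passed camera's preset test and none with an estimated correlation. Other splits of the 6 AGS libraries passed up to 6 lists in the preset test, so its adjusted p-values alone do not set the real split apart. Of 21 members of the miR-17 to miR-92 cluster and its paralogs 13 fell (14 adjusted over the list alone) and miR-363-3p rose (adjusted p = 2.07e-05, and 0.199 with an estimated correlation). Of 20 let-7 members 7 fell (8 adjusted over the list alone; adjusted p = 0.00191, and 0.286 with an estimated correlation). In the miR-34 and miR-449 family miR-449a, miR-449b-5p and miR-449c-5p rose and miR-34a-5p fell from 287 ± 15.4 to 173 ± 16.1 CPM, the same counts when adjusted over the list alone (adjusted p = 0.00238, and 0.156 with an estimated correlation). In the miR-99, miR-100 and miR-125 list miR-125a-3p, miR-125b-2-3p, miR-99a-3p and miR-99b-3p of 11 fell (adjusted p = 0.0439, and 0.199 with an estimated correlation), a call lost without AGS DMSO 3 (adjusted p = 0.0801), with a minimum of 10 CPM (0.0672) and with the more abundant arm of each hairpin alone (0.256). In the DLK1-DIO3 cluster 7 of 25 members rose and 0 fell (adjusted p = 4.11e-04, and 0.574 with an estimated correlation), or 14 without the 3 libraries that stood apart and 15 without HGC-27 SAHA 2. Its most abundant member, miR-381-3p, stood at 30.1 ± 17.8 CPM with DMSO and 145 ± 32.2 CPM with SAHA (2.26, adjusted p = 0.188). With plain totals, 7 members were called lower in the miR-17 to miR-92 list, 5 lower and 1 higher in the let-7 list, and 2 lower in the miR-99, miR-100 and miR-125 list, with negative medians.

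The remaining lists did not pass in AGS. Their called members were miR-182-5p and miR-183-5p higher in the miR-183 cluster (adjusted p = 0.615), miR-195-3p lower in the miR-15 and miR-16 family (0.521), miR-30c-1-3p, miR-30e-3p and miR-30e-5p lower in the miR-30 family (0.154, 0.0348 without AGS DMSO 2, and 0.0419 without the 3 libraries that stood apart), and miR-301a-3p lower in the miR-130 and miR-301 family (0.239). In the miR-181 family (0.615) miR-181a-3p and miR-181b-3p were higher and miR-181a-2-3p, miR-181b-2-3p and miR-181c-3p lower. With plain totals the medians of the miR-15 and miR-16, miR-30 and miR-181 lists turned from negative to positive in AGS. Plain totals also gave 1 member higher and 2 lower in the miR-23, miR-24 and miR-27 clusters, 2 lower among HOX cluster microRNAs, 0 lower in the miR-130 and miR-301 family, 1 higher for miR-221 and miR-222, 3 higher in the Xq27 testis cluster, 2 higher among microRNAs made without Drosha and 1 lower among those reported as silenced. miR-23a-5p, miR-27a-5p and miR-27b-5p were lower in the miR-23, miR-24 and miR-27 clusters (0.053, and 0.0144 without AGS DMSO 1), and miR-10a-3p, miR-196a-3p and miR-196b-5p among HOX cluster microRNAs (0.127, and 0.0284 without AGS DMSO 1). Higher were miR-516a-5p and miR-516b-5p in the chromosome 19 cluster (0.881, and 0.00105 without AGS SAHA 2) and miR-508-3p and miR-509-3-5p in the Xq27 testis cluster (0.0811, and 0.0137 without AGS SAHA 2). miR-194-3p rose in the miR-192, miR-194 and miR-215 list (0.406, 0.0488 without AGS DMSO 2, and 0.0151 without the 3 libraries that stood apart, where 4 of 4 tested members were higher). miR-199b-5p, miR-199a-3p and miR-199b-3p rose among the 8 fibroblast and smooth muscle markers (0.0597, 0.0348 without AGS DMSO 2, 0.0243 with a minimum of 10 CPM, and 0.00589 without the 3 libraries that stood apart). Of the microRNAs reported as silenced by DNA methylation (0.521), miR-129-5p and miR-148a-5p rose and miR-181c-3p and miR-195-3p fell. This list had 5 members higher without HGC-27 SAHA 2 (0.198), and passed without the 3 libraries that stood apart, with 8 higher and 1 lower (0.0227). miR-1224-5p was higher among microRNAs made without Drosha (0.615), and miR-1246, miR-1260a and miR-1260b were higher and miR-4454 lower among entries that overlap other small RNAs (0.615). No member was called in the miR-200 family (0.881), the miR-29 family (0.346), miR-221 and miR-222 (0.881), the blood cell markers (0.615) or the markers of muscle, liver and neurons (0.615). The miR-183 cluster had 0 members called without HGC-27 SAHA 2, whereas 5 of 9 HOX cluster microRNAs were lower (0.0567) and 8 of 20 members of the chromosome 19 cluster higher (0.3). Of these called members, miR-182-5p lost its call without any 1 of 5 AGS libraries, all but AGS DMSO 3, and miR-183-5p and miR-1260b without the same 5. miR-199a-3p and miR-199b-3p lost theirs without any 1 of the 6 AGS libraries, miR-509-3-5p without any but AGS SAHA 2 or AGS DMSO 2, miR-194-3p without AGS SAHA 1, AGS SAHA 2 or AGS DMSO 1, miR-148a-5p without AGS SAHA 1, AGS SAHA 3 or AGS DMSO 1, miR-508-3p without AGS DMSO 1, and miR-1260a without any but AGS DMSO 2 or AGS DMSO 3. miR-372-3p, the tested embryonic stem cell microRNA, rose from 0.534 ± 0.482 to 3.77 ± 1.56 CPM, a call lost without AGS SAHA 1, AGS SAHA 3, AGS DMSO 1 or AGS DMSO 2.

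The count of calls in AGS was 97, 100 and 104 without AGS DMSO 1, AGS SAHA 1 and AGS SAHA 2, and 166 (92 higher, 74 lower) without the 3 libraries that stood apart. The split into higher and lower calls moved both ways: 116 higher and 37 lower with plain totals and 117 and 38 in limma-trend on the authors' normalized values, but 59 and 112 with annotated and predicted entries fitted together and 90 and 150 with all deposited entries. It was 39 and 61 without AGS SAHA 1 and 61 and 84 without AGS DMSO 2.

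**Figure D3:**
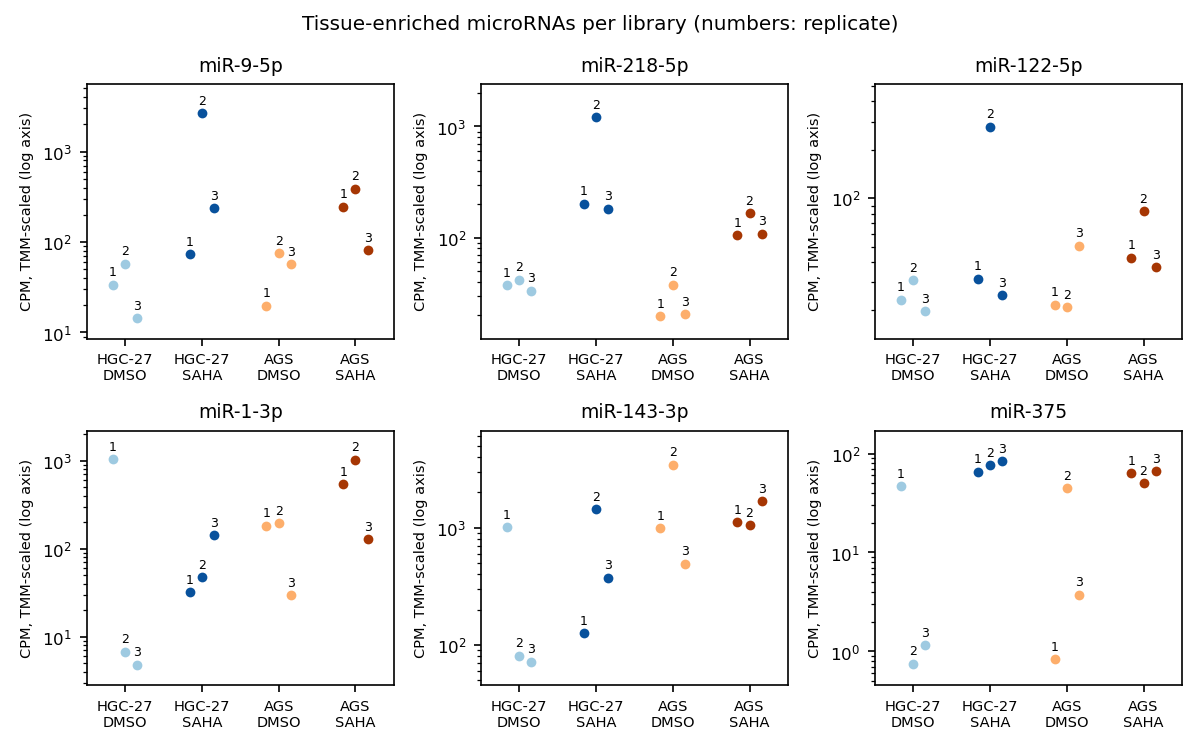
Levels of microRNAs known from brain, liver, muscle, fibroblasts or endocrine cells in each library, in CPM on a log axis with the replicate number beside each point. HGC-27 SAHA 2, HGC-27 DMSO 1 and AGS DMSO 2 hold some of them far above their replicates, such as miR-9-5p at 2658 CPM in HGC-27 SAHA 2.

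Much of the response was shared by the lines. miR-449c-5p, miR-184 and miR-891a-5p rose in both, miR-184 from 1.96 ± 2.32 to 79.2 ± 3.12 CPM in HGC-27 (log2 fold change 5.24, adjusted p = 9.15e-05). Together with miR-370-3p and miR-1298-5p they were the 5 shared rises with the largest smaller change. The 5 shared falls of this kind were miR-92a-1-5p, let-7c-3p, miR-152-5p (-1.23 in HGC-27), let-7e-3p (-1.14 in AGS) and miR-20a-3p (-1.14 in HGC-27). In all, 64 microRNAs were called higher in both lines (19.8 expected if the lines were independent, one-sided Fisher's exact p = 2.45e-28) and 53 lower in both (13.4 expected, p = 5.15e-29). These 2 p-values treat the microRNAs as independent, which they are not, so they are too small. They also measure no spread between libraries. Only miR-7-5p and miR-195-3p were called in opposite directions, against 32.6 expected. Across the 608 microRNAs, which are not independent of each other, the log2 fold changes of the lines had a Pearson correlation of 0.756 and a Spearman correlation of 0.696, and 456 had the same sign. The lines had no control libraries in common. The shared count was 79 without AGS SAHA 2 and also without AGS DMSO 1, and 106 without the 3 libraries that stood apart.

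**Figure D4:**
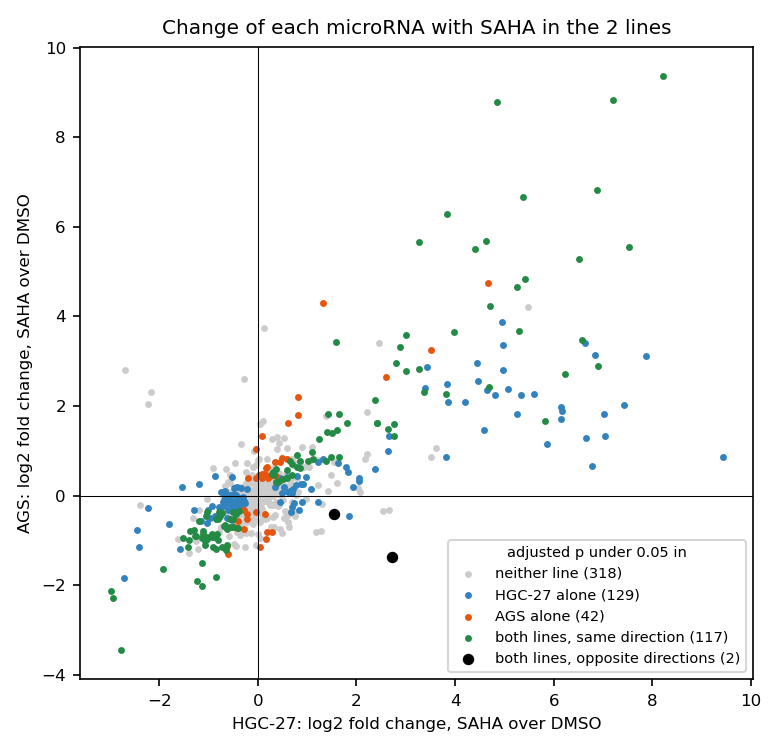
Log2 fold change with SAHA in AGS (vertical axis) against that in HGC-27 (horizontal axis) for the 608 microRNAs tested, coloured by the line in which they were called. The 117 microRNAs called in the same direction in both lines lie at the upper right (64) and the lower left (53).

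The responses of the lines differed for 11 microRNAs, 6 with a higher and 5 with a lower log2 fold change in AGS. miR-7-5p, a repressor of the EGF receptor, rose by 1.54 in HGC-27 and fell by 0.42 in AGS, from 21770 ± 3661 to 16310 ± 895 CPM (adjusted p = 0.0468), a difference of -1.95 (adjusted p = 5.82e-04). Of the 3 hairpins listed for miR-7-5p, that with the most counts lies on chromosome 9 between 83969748 and 83969857 and overlaps an exon of HNRNPK. miR-1247-3p fell from 71.9 ± 12.5 to 24.9 ± 3.25 CPM in HGC-27 and stood at 55.0 ± 3.35 and 62.5 ± 4.72 CPM in AGS (difference 1.71, adjusted p = 0.00271). miR-135b-3p fell from 125 ± 8.38 to 54.2 ± 7.003 CPM in HGC-27 and stood at 6.10 ± 0.54 and 7.31 ± 0.987 CPM in AGS (1.45, adjusted p = 0.00827), and miR-516a-5p rose from 164 ± 25.8 to 335 ± 33.2 CPM in AGS and stood at 81.1 ± 4.9 and 78.9 ± 4.79 CPM in HGC-27 (1.07, adjusted p = 0.0112). miR-19a-3p fell from 405 ± 81.4 to 208 ± 14.8 CPM in AGS but not in HGC-27 (427 ± 60.6 and 478 ± 50.3 CPM), a difference of -1.13 (adjusted p = 0.0263). miR-27a-5p differed by -1.10 (adjusted p = 0.0105), miR-195-3p by -4.11 (adjusted p = 0.01), miR-1247-5p by 1.301 (adjusted p = 0.0263), miR-30a-3p by 0.51 (adjusted p = 0.0288) and miR-676-3p, which rose in both lines, by 1.85 (adjusted p = 0.0472). miR-216b-5p rose at least 5.67-fold in HGC-27, where DMSO libraries listed none, and was not called in AGS (9.18 ± 4.49 and 14.8 ± 2.05 CPM, adjusted p of the difference 0.0105).

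The number of such differences was sensitive to the test: 37 with DESeq2, 27 with limma-trend on the authors' values, and 2 without HGC-27 DMSO 3 (14 to 20 without AGS SAHA 3 or AGS DMSO 3). miR-7-5p and miR-1247-3p were called in every alternative run, and they alone kept their calls without HGC-27 DMSO 3. miR-676-3p and miR-1247-5p kept theirs only without AGS SAHA 3 or AGS DMSO 3 when 1 library was left out. In camera's preset test 4 lists differed: the responses of miR-221 and miR-222 (adjusted p = 0.0111) and of miR-99, miR-100 and miR-125 (0.0435) were higher in AGS, and those of miR-192, miR-194 and miR-215 (0.0111) and of the microRNAs reported as silenced by DNA methylation (0.00642) were lower. With an estimated correlation the adjusted p of each was 0.473.

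Before treatment the lines differed widely. Under DMSO, miR-135b-3p and miR-135b-5p, from an intron of LEMD1 on chromosome 1, were lower in AGS than in HGC-27 (adjusted p = 1.49e-08, with a log2 difference of -4.34, and 6.33e-06), the latter at 50.6 ± 14.7 against 407 ± 66.6 CPM. miR-181d-5p stood at 461 ± 43.5 CPM in AGS and 2591 ± 87.6 CPM in HGC-27 (-2.49, adjusted p = 1.29e-08), and the HOX cluster microRNA miR-10a-5p at 7511 ± 1320 and 24090 ± 2031 CPM (-1.68, adjusted p = 2.94e-06). AGS had more miR-100-5p (60050 ± 8485 against 34660 ± 1790 CPM, log2 difference 0.79, adjusted p = 3.01e-04) and miR-27b-3p (41940 ± 3070 against 21670 ± 1239 CPM, 0.95, adjusted p = 8.84e-06). In all 271 microRNAs were called, 149 higher and 122 lower in AGS, and 105 and 63 differed 2-fold or more. The replicates of the lines did not overlap for 336 microRNAs (55.3%, where chance gives 10%).

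Some microRNAs were listed in AGS alone under DMSO. miR-514a-3p was at least 34.1-fold, miR-509-3-5p at least 24.6-fold and miR-3667-3p at least 22.2-fold higher in AGS, and the ratio of counts was 99.4 for miR-3622a-5p (95% interval 27.0 to 829, or from 18.95 with 1 count in each blank library). miR-4454 (4.02), miR-466 (4.00), miR-195-3p (3.77) and miR-190b (3.11) were also among the 8 highest, and miR-296-3p (-3.68), miR-676-3p (-3.38), miR-504-5p (-3.33), miR-3909 (-2.29) and miR-26b-3p (-2.24, a call lost without AGS DMSO 2) among the 8 lowest. Of the most abundant microRNAs, miR-21-5p was higher in AGS (0.47, adjusted p = 0.00343), let-7i-5p missed the threshold (0.19, adjusted p = 0.128), and miR-30a-5p (-0.64), let-7g-5p (-1.02), miR-92a-3p (-1.11) and miR-148a-3p (-1.37) were lower. The call of miR-148a-3p was lost without HGC-27 DMSO 2 or AGS DMSO 1.

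Of the lists, 3 differed between the untreated lines in camera's preset test. All 4 tested members of the Xq27 testis cluster were higher in AGS (adjusted p = 0.0166, and 0.386 with an estimated correlation), as were 5 of 6 in the chromosome 19 cluster (adjusted p = 0.0255, and 0.444 with an estimated correlation). Of 11 miR-30 members 7 were lower in AGS, or 9 adjusted over the list alone (adjusted p = 0.0255, and 0.386 with an estimated correlation). The miR-200 family had 0 of 6 members called (adjusted p = 0.987).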

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

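The tests of random lists, marker medians, scaling, carry-over, counting error and the thinning of all libraries were chosen only after the results they concern were seen, but not the thinning of the HGC-27 SAHA libraries or the splits. No explanation from biology was tested for the libraries that stood apart, since the labels name no group that would set them apart.

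The difference between the responses of AGS and HGC-27 passed its test for 11 microRNAs, which is why they are listed here. The log2 fold change was higher in AGS by 1.85 for miR-676-3p, 1.71 for miR-1247-3p, 1.45 for miR-135b-3p, 1.301 for miR-1247-5p, 1.07 for miR-516a-5p and 0.51 for miR-30a-3p. It differed by -4.11 for miR-195-3p, -1.95 for miR-7-5p, -1.13 for miR-19a-3p and -1.10 for miR-27a-5p, and for miR-216b-5p the fitted difference of -6.10 depends on the prior count, since no HGC-27 DMSO library listed it. Of 100 drawn labelings of the libraries within lines, 6 gave as many calls as the 11, the real one included, the highest other gave 122, and each of these others kept the real split in HGC-27 alone. Such a labeling carries the SAHA effect of 1 line into the difference, so the labelings cannot tell whether chance gives this count.

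The predicted entries, which the comparisons of the report did not use, also differed between SAHA and DMSO, with 106 of 258 called in HGC-27 (81 higher, 25 lower) and 59 in AGS (44 higher, 15 lower). Of all 860 predicted entries 284 share their 12 counts with another entry, but of the 258 tested only 24. The splits of 6 libraries, 10 in number, are too few for a share under 0.05: the real split was 1 of 10 with as many calls in either line, against at most 0 calls in HGC-27 and 5 in AGS for the others.

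HGC-27 SAHA 2 held 42 microRNAs at 10 CPM or more and at least 4-fold above both of its replicates, among them miR-9-5p (2658 CPM against at most 236 CPM), miR-381-3p (1793 against at most 56.2 CPM), miR-218-5p (1214 CPM), miR-451a (397 CPM) and miR-122-5p (279 CPM). Unequal depth is excluded, since 41 stood out after the replicates were thinned to the depth of this library. It was the shallowest of its group and kept all of its counts, so the thinning did not test its own counting noise. That noise is excluded by exact binomial tests against both replicates, with a highest p of 0.00566 (miR-145-3p) after Bonferroni adjustment over all tested microRNAs. A candidate explanation is RNA from other tissues: over 20 markers of blood, fibroblasts, muscle, liver and neurons the median log2 ratio to the replicates was 1.63, at percentile 100 of 10000 matched random lists. Some of these markers, such as miR-122-5p, miR-124-3p and miR-451a, are themselves among the 42. The members of the random lists were drawn independently, whereas markers were correlated (estimated at 0.68 for those of fibroblasts and smooth muscle in HGC-27). Such percentiles are therefore too extreme. A list of 15 brain-enriched microRNAs gave a higher median of 2.62 (percentile 100), but it was written after the members were seen and so cannot tell brain from other sources.

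In both lines 28 microRNAs had a fitted rise of 4-fold or more with SAHA, such as miR-449c-5p, miR-184 and miR-891a-5p, although 5 of them were listed in no DMSO library of a line and bounded there at only 1.96-fold to 3.996-fold (miR-889-3p, miR-3689f, miR-449b-5p, miR-1224-5p and miR-758-3p). In HGC-27 SAHA 2, the members miR-129-5p, miR-1298-5p, miR-134-5p, miR-218-5p, miR-370-3p and miR-409-3p stood at least 4-fold above both replicates. For miR-218-5p this was 1214 against at most 202.8 CPM. RNA from other tissues cannot be told apart from a response: the median of 19 markers reached a log2 ratio of 2 in 0 of 6 SAHA libraries (-1.60 to 1.84, with the raised microRNAs at 2.43 to 2.72), but the markers went both ways (SD 0.85 to 2.35), and against DMSO without HGC-27 DMSO 1 and AGS DMSO 2 their medians were 0 to 2.64 and lay under 2 by more than their SD in only 3 libraries. Thinned to 2284193 counts per library, 12 of 12 members at 10 CPM or more in SAHA of both lines were still called higher in both, which excludes depth for these, but for members at a lower level (9 of 16 still called) depth and counting noise cannot be told apart from a response. The choice among the 3 scalings cannot account for the rises, since it moved the median log2 fold change of all microRNAs by at most 0.19 in a line. The members, chosen for large rises under TMM, had a lowest median of the fitted log2 fold changes of 3.92 over these scalings and both lines. With unlisted members at their bound it was 3.27.

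HGC-27 DMSO 1 and AGS DMSO 2 held 8 and 3 microRNAs at 10 CPM or more and at least 4-fold above both replicates, among them miR-1-3p (1035 CPM against at most 6.78 CPM in HGC-27), miR-143-3p (1010 against at most 80.9 CPM in HGC-27), miR-215-5p (372 against at most 70.7 CPM in AGS) and miR-375 (44.3 against at most 3.75 CPM in AGS). AGS DMSO 2 was set apart by little, since on CPM of plain totals it held 3 such microRNAs, AGS SAHA 2 held 2 (with the brain list at percentile 99.99) and AGS DMSO 3 held 1. Carry-over from a SAHA library of the line is excluded, since strongly raised microRNAs imply at most 4.04% in HGC-27 and 16.4% in AGS, where the members need at least 60.9% and 62.9%. Counting noise is excluded, with 11 of 11 members beyond counting error. A candidate explanation is RNA from other tissues, whose 20 markers had median log2 ratios of 1.86 and 0.32, with a lower percentile of 98.4 among matched random lists (98.3 in a second draw of such lists). The 3 members in AGS DMSO 2 (miR-215-5p, miR-219a-2-3p and miR-375) are not among these markers, so the median of 0.32 does not bear on them. The brain list had 0.66 there (percentile 100). High percentiles also came with small shifts, such as 99.54 for the brain list at 0.17 in HGC-27 DMSO 2. However, the brain list lay at percentile 99.54 or higher in the replicate 2 library of every group. In every other library it lay at 42.52 or lower. High values of this list thus went with the replicate number in both lines and treatments, and the cause was not tested. The limit given above for the random lists holds for these percentiles too.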

How the results depend on the processing

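The settings that used all deposited entries, fitted annotated and predicted entries together, summed hairpins or left out the 3 libraries that stood apart were chosen after the data were seen. The cause of the changes below was not tested unless a sentence gives it.

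The count of calls for SAHA in HGC-27 (248) became 131 with a 2-fold minimum and 384 with all deposited entries, which test more entries, and 163 to 210 when each replicate was left out. In AGS (161) it became 70 with a 2-fold minimum, and 97 to 145 without a replicate. For AGS against HGC-27 under DMSO (271) it was 168 with the minimum, 467 with all entries, and 228 to 277 without a replicate, and for the shared calls (117) it was 51, 176, and 79 to 110. The difference between the lines (11 calls) was the least stable: 37 with DESeq2, 27 with limma-trend on the authors' values, 50 with all entries, 19 with annotated and predicted entries together, and 2 to 20 without a replicate.

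Of the lists, 14 passed camera at its preset correlation in the lines together, 0 with an estimated correlation, 30 in fry and 10 with the more abundant arm of each hairpin alone, and 14 to 20 when a replicate was left out. Of the named results called, 148 in number, 2230 of 2548 runs of alternatives gave the same call and 318 a weaker one, with 0 reversed, and 92 results were the same in all runs. Of 120 named results not called, only 27 were the same in all of their runs. In 96 of 2021 runs such a result became called in its direction, and 2 runs reversed the direction past the threshold: miR-1-3p in HGC-27 went from -2.23 to 3.99 when the 3 libraries that stood apart were left out, and lay between -3.13 and 3.72 when each replicate was left out, with 3.72 without HGC-27 DMSO 1, the DMSO library that held most of its counts.

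With the replicate number as a block the difference between the lines had 6 calls, HGC-27 218, AGS 147, the baseline 264 and the shared calls 111. The residuals of libraries with the same number had correlations of -0.32 to 0.50, and those of SAHA and DMSO of 1 line -0.32 to 0.07, so the numbers give no sign of a pairing within a line. Of the 18 pairs with the same number 7 lay above 0.1, against 0 of the 6 within a line. The highest, 0.50, was that of HGC-27 SAHA 2 with AGS SAHA 2. Pairs of unlike numbers reached 0.46 (HGC-27 SAHA 1 with AGS SAHA 3). Whether the numbers mark a grouping across the lines cannot be told from these values.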

Other observations

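The tests on the arms of a hairpin were chosen only after the fold changes were seen. Those on neighbouring hairpins and on level were not.

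The splits of 6 libraries number 10, too few for a share under 0.05. With 1 split as large, the real one, SAHA gave 248 calls in HGC-27 against at most 0 in another split, 161 in AGS against at most 16, and AGS against HGC-27 under DMSO 271 against at most 1. For the list tests 3 splits in HGC-27 passed as many lists as the real 9 (highest other 10), and 4 in AGS as many as the real 5 (highest other 6). The preset test thus passed lists in wrong splits as well. The list tests of the baseline and of the difference between the lines were not run on splits. For the calls shared by the lines, 1 of 100 drawn labelings, the real one, gave as many as 117 (highest other 3). Libraries grouped at random within lines therefore did not give this count. Since other splits gave at most 0 calls in HGC-27 and 16 in AGS, the labelings cannot tell whether the lines share more calls than chance gives.

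Both arms of a hairpin changed together, with a Pearson correlation of 0.861 in HGC-27 and 0.602 in AGS over 138 hairpins (Spearman 0.67 and 0.56). This remains a hypothesis since it was found and tested on the same data. HGC-27 SAHA 2, which held both arms of miR-127 and of miR-9 far above its replicates, was not left out. The less abundant arm did not fall further than the other by any marked amount (median log2 difference -0.0497 and -0.11, lower in 75 and 80 of 138 hairpins). Hairpins within 10 kb on 1 strand changed together, with a Spearman correlation of 0.679 in HGC-27 and 0.499 in AGS over 66 pairs without the DLK1-DIO3 cluster, where 0 of 1000 shuffles came as high (95th percentile 0.202 and 0.189). Whether microRNAs at a low level rose more could not be decided, with Spearman correlations of -0.16 in HGC-27 and -0.12 in AGS over 356 microRNAs.

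Chosen after their values were seen, 3 microRNAs known from the epididymis, which lie in a cluster at Xq27, rose in both lines. miR-891a-5p was at least 15.6-fold higher in HGC-27 and 22.4-fold in AGS, miR-892a at least 9.71-fold higher in HGC-27 and from 3 counts to 149 in AGS, and miR-888-5p went from 2 counts to 50 in HGC-27 (ratio 31.8, 95% interval 8.36 to 270.0) and from 3 to 60 in AGS (20.1, 6.57 to 100.4). With 1 count in each blank library the lower limits were 12.6 for miR-892a in AGS and 5.84 and 4.899 for miR-888-5p in HGC-27 and AGS.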
